A study of Homo sapiens with 4 samples.

How the data were processed

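RNA sequencing libraries of LP-1 cells, 2 from HRP2 knockdown and 2 from non-target control cells, were made from Trizol-extracted RNA by BGI protocols, per the labels. The submitters' processing notes name BWA, Bowtie2 and RSEM and the genome build hg19, without saying which tool did which step. Versions, annotation, strandedness, filters, the normalization of the libraries and the test behind the Q values are not given in the sources used here.

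Values of 2 kinds were used. The log2 fold changes are the authors' own, per the file headers, computed as knockdown over control from the group stems of the sample titles, at the level of genes (684) and of transcripts (1040). The Q value beside each of them is likewise as deposited by the authors, and every one was under 0.05 (largest 0.0495 for genes and 0.0497 for transcripts), so genes and transcripts that did not pass are absent from both tables and have no value here. The other fields taken from the deposited tables are names: one table lists 210503 gene identifiers with symbol and RNA type, among them 24237 mRNA genes, and another lists 439 transcript identifiers, all of them from the 510 lower transcripts of the transcript comparison. These lists carry no numbers and served only to match symbols. No per-library value entered any step. The planned tests on counts, or on normalized expression, were therefore not run, and neither were the planned gene set tests with a preset or an estimated correlation; the design was kept as fixed before the data were examined, and the authors' values were described in its place. A count adjusted over the list alone could not be made, since uncalled genes have no p-value. The depth of each library is unknown.

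Gene IDs were taken as deposited, and 681 of 684 matched a gene of the RefSeq table for GRCh38.p14, which was used for names, for chromosome membership and for which genes are neighbours. Coordinates are not printed, because that build differs from the authors'. Among the symbols of the transcripts, 3 had been turned into calendar dates by a spreadsheet, of which 2 were restored from their accessions; the remaining 1 and another 1 with an empty symbol were left out where transcripts are set against genes. Transcript GC content and length were medians over the protein-coding transcripts of each gene in GENCODE 29, or over all its transcripts where none was protein-coding, and 677 of the 684 genes had a value. The share of a gene's sequence found in other genes was the percent of the 31-nucleotide words of its longest such transcript that occurred in a transcript of another gene. Genes at 50% or more, or with a readthrough name, were treated as sharing sequence (35 genes).

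Before the data were examined, 44 gene lists were fixed from general knowledge of myeloma, chromatin, protein quality control, metabolism and cell types, and symbols were matched to the deposited identifiers, older symbols included. For each list the called members were counted by direction. The 9 lists with at least 5 called members were tested by a two-sided Fisher's exact test of higher against lower, set against all other called genes, with Benjamini-Hochberg adjustment. Neither this test nor the limit of 5 called members was in the design fixed before the data were examined. That design planned gene set tests on values per library, for lists with at least 5 tested members. The direction test asks about direction among called genes. It does not ask whether a list is called more often than other genes, which would need the expressed genes as background. It treats genes as independent, which coregulated genes are not, so its p-values are over genes and not over samples. On simulated directions for the 684 genes the test called at most 4.1% of lists of any size used when direction was random, and a list needed 6 called members, all higher, to be called in every one of 1000 simulations. Random directions carry neither coregulation nor the trend with GC content described in the results. The 4.1% is therefore not the error rate for the lists tested here.

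The genes named in the text follow a rule fixed before the data were examined: HDGFL2, RIOX2, NSD2, FGFR3 and PSIP1, the 12 largest changes in each direction, and up to 4 members of each list by Q value. The parts of that rule that need expression levels or libraries, a minimum expression and no overlap between groups, could not be applied. Further list members, NDUFA4L2 in the metabolic paragraph and the transcripts named singly were chosen after their values were seen. Some genes that the rule names are not reported here. Alternatives on the deposited tables were a Q value under 0.01, an absolute log2 fold change of at least 1, leaving out genes that share sequence, an exact binomial test in place of Fisher's, comparison within 8 strata of GC content (4) and length (2), leaving out the chromosome with most of a list's called members, adjustment over all 29 lists with a called member, and the transcript table. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.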

Results

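The transcriptome of LP-1 cells, an established human multiple myeloma line, was profiled by RNA sequencing after transduction with a lentiviral guide RNA construct against HRP2 or with a non-target control construct. HRP2 is the chromatin reader encoded by HDGFL2, and the series title pairs it with MINA, the product of RIOX2, in a study of the epigenome of t(4;14) myeloma and its sensitivity to proteasome inhibitors. The design held 4 libraries in 2 groups, 2 of HRP2 knockdown cells and 2 of control cells. The measurements used here are the authors' deposited gene table and transcript table, each of which gives a log2 fold change of knockdown over control and a Q value, without a standard error. Values per library were not used here, so the spread between the 2 libraries of a group is not known, the sequencing depth behind each value is unknown, and no fold change below carries an SD. Nothing in the labels says that the libraries of a group came from separate cultures, so the Q values may measure technical spread alone.

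The targeted transcript was lower in the knockdown. HDGFL2 (gene ID 84717) had a log2 fold change of -1.37 in the authors' deposited table, which leaves 0.388 times the control level, with a Q value of 2.99e-13. The labels name a guide RNA without saying whether the gene was edited or repressed, so this value measures the transcript and not the loss of HRP2 protein. FGFR3, the receptor tyrosine kinase gene that the t(4;14) translocation places under immunoglobulin control, was lower as well, at 0.455 times the control level (log2 fold change -1.14, Q = 8.73e-08) in the same deposited table. The other gene activated by that translocation, NSD2, which encodes an H3K36 methyltransferase, was not among the genes of the authors' deposited table, nor were RIOX2 or PSIP1, the gene of the HRP2 paralogue LEDGF. HDGF, another member of the HRP2 family, was higher, with a log2 fold change of 0.49 (Q = 0.0334, authors' deposited table). Since the table held no gene with a Q value of 0.05 or more, the size of the difference for RIOX2, NSD2 and PSIP1 is not known. At the transcript level the authors' deposited table gave -1.34 for HDGFL2 (Q = 0.0203) and -1.39 for FGFR3 (Q = 0.0197).

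In all, 684 genes passed the authors' threshold, 361 of them higher and 323 lower in the knockdown. Of these, 682 were annotated as mRNA genes, 1 as a long non-coding RNA gene and 1 as a pseudogene. Most changes were modest. The authors' deposited table gave an absolute log2 fold change under 1 for 535 genes (78.2%), and 58 higher and 91 lower genes reached at least 1. The median log2 fold change was 0.66 for higher genes and -0.78 for lower genes. Lower genes had the larger changes, by a median of 0.12 in absolute log2 fold change (two-sided permutation test over genes, p = 1e-05, the smallest that 100000 permutations can give), although genes are not independent replicates.

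**Figure D1:**
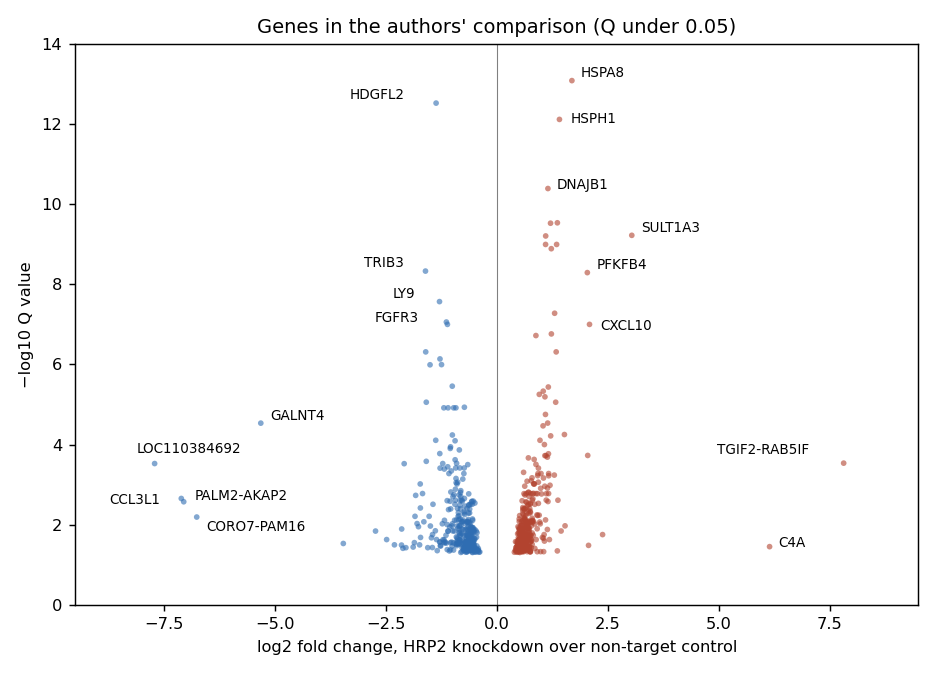
Log2 fold change of HRP2 knockdown over non-target control (x axis) against the −log10 of the authors' Q value (y axis) for the 684 genes of the authors' deposited gene table, 1 point per gene, red higher and blue lower in the knockdown. HSPA8 has the smallest Q value, followed by HDGFL2, and 9 genes lie at an absolute log2 fold change of at least 3.

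Named by size of change alone, the 12 highest genes in the authors' deposited table were TGIF2-RAB5IF at 7.82, C4A at 6.15, SULT1A3 at 3.04, LOC101928589 at 2.38, CXCL10 at 2.09, SLC25A21 at 2.07, AK4 at 2.05, PFKFB4 at 2.04, HSPA8 at 1.69, CAVIN4 at 1.54, BNIP3 at 1.52 and HSPA6 at 1.45 (log2 fold changes). CXCL10 encodes an interferon-inducible chemokine, AK4 a mitochondrial adenylate kinase, PFKFB4 a glycolytic regulator, BNIP3 a mitophagy receptor, and HSPA8 and HSPA6 are HSP70 chaperone genes. The 12 lowest in the authors' deposited table were LOC110384692 at -7.71, CCL3L1 at -7.11, PALM2-AKAP2 at -7.05, CORO7-PAM16 at -6.76, GALNT4 at -5.32, DGCR6 at -3.46, MKX at -2.73, MEI1 at -2.48, LOC102724378 at -2.31, CLIP2 at -2.15, NDUFA4L2 at -2.14 and TRIB1 at -2.12. Several of these cannot be read as changes of single genes. TGIF2-RAB5IF, CORO7-PAM16 and PALM2-AKAP2 are readthrough loci, and C4A, SULT1A3 and GALNT4 share 95.4%, 98.6% and 93.2% of their transcript sequence words with another gene, so that reads could be split between copies during counting. HSPA6 shares 56.7% in the same way.

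The cytosolic heat shock genes moved together. Of the 18 genes on this list, 12 were in the authors' deposited table, and all 12 were higher in the knockdown, with a median log2 fold change of 1.16 and a range of 0.59 to 1.69. HSPA8, the constitutive HSP70, was raised to 3.23 times the control level (Q = 8.21e-14), and HSPH1, an HSP110 exchange factor, to 2.66 times (Q = 7.64e-13) in the authors' deposited table. DNAJB1 and DNAJA1, HSP40 co-chaperones, had log2 fold changes of 1.15 (Q = 4.06e-11) and 1.21 (Q = 2.98e-10) there, and HSP90AA1, CHORDC1, AHSA1 and HSPE1 lay at 1.16, 1.35, 1.08 and 1.07. HSPA1B was at 1.23 but shares 74.4% of its sequence words with other genes. Other called genes were higher in 51.9% of cases, and the list differed from them by Fisher's exact test (two-sided, adjusted p = 0.00484 by Benjamini-Hochberg over the 9 lists with at least 5 called members, and 0.0156 over all 29 lists with a called member).

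Called genes of the other protein quality control lists went both ways. From the ATF6 and XBP1 arm of the unfolded protein response, 6 of 26 genes were in the authors' deposited table and all 6 were lower, with a median log2 fold change of -0.81. They included DNAJB9, an endoplasmic reticulum HSP40, at -1.28 (Q = 7.28e-07), WFS1 at -0.94, SYVN1, the ubiquitin ligase of ER-associated degradation, at -0.81 and SEC24D, a COPII coat gene, at -0.80 (authors' deposited table). Fisher's exact test against the other called genes gave an adjusted p of 0.0297 over 9 lists and 0.0957 over 29 lists. The list did not pass by an exact binomial test (adjusted p = 0.0563). It did not pass either with the 3 members at a Q value under 0.01 (adjusted p = 0.223, Fisher's exact test) or the 1 at an absolute log2 fold change of at least 1. All of these were lower, and so few members cannot pass even when all go one way. In the ATF4 and CHOP arm 3 of 29 genes were called, with TRIB3, a pseudokinase induced by stress, at -1.61 (Q = 4.67e-09), CEBPB at -1.28 and DDIT4 at 0.60. Of the 41 proteasome subunits and activators, the targets of the drugs named in the series title or their partners, 2 were called, PSMD1 at 0.45 and PSME4 at 0.51 in the authors' deposited table. Among 25 ubiquitin and autophagy genes 4 were called, all lower, among them WIPI1, an autophagy gene, with a log2 fold change of -0.84 in the authors' deposited table. Of 23 NRF2 and oxidative stress genes, PRDX1 was higher at 0.61 and OSGIN1 lower at -1.14.

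The called glycolytic and hypoxia-responsive genes were higher. The authors' deposited table held 10 of the 33 genes on this list, all 10 higher, with a median log2 fold change of 0.73. PFKFB4 and PFKFB3, which set the level of the glycolytic activator fructose-2,6-bisphosphate, had log2 fold changes of 2.04 (Q = 5.1e-09) and 1.20 (Q = 0.00104). BNIP3 lay at 1.52 and P4HA1, a collagen prolyl hydroxylase, at 1.10 (Q = 6.2e-10), and the glycolytic enzyme genes ENO1, PGK1, TPI1 and PGAM1 lay between 0.72 and 0.73 in the authors' deposited table. The direction differed from that of the other called genes, of which 52.1% were higher (Fisher's exact test, adjusted p = 0.00941 over 9 lists and 0.0303 over 29 lists). With fewer members the list did not pass, although each remaining member was higher: 6 of 6 with a Q value under 0.01 (adjusted p = 0.138, exact test), 4 of 4 with an absolute log2 fold change of at least 1 (0.0861) and 6 of 6 without the chromosome that holds most of its called members (0.11). That chromosome, 10, had the largest share of called genes higher, 24 of 28 (85.7%), the members of this list included. NDUFA4L2, a gene outside this list among the 12 lowest, had a log2 fold change of -2.14 in the same table.

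Cholesterol synthesis genes were mostly higher, 9 of the 10 called out of 31. MSMO1, a sterol demethylase gene, had a log2 fold change of 1.08 and SQLE, which encodes squalene epoxidase, 0.84 (Q = 0.000235) in the authors' deposited table. The exception was SREBF1, a lipogenic transcription factor gene, at -0.73 (Q = 1.17e-05). Of the 13 MHC class II genes on the list, 7 were called and all 7 were higher, with log2 fold changes from 0.50 for HLA-DRA to 0.74 for HLA-DMA in the authors' deposited table. These 7 genes lie on 1 chromosome. The class II genes HLA-DQA2, HLA-DRB3 and HLA-DRB4 were also called, but they were outside the list and their directions are not given here. None of 15 genes of the MHC class I list was called. Each of the cholesterol and class II lists had an adjusted p of 0.0297 over 9 lists and of 0.0957 over 29 lists (Fisher's exact test). With a Q value under 0.01 neither passed (4 of 5 higher, adjusted p = 0.373, and 4 of 4 higher, 0.223, Fisher's exact test), but so few members cannot pass even when all are higher. The cholesterol list did not pass without genes sharing sequence (8 of 9 higher, adjusted p = 0.0599, Fisher's exact test). Its 1 member at an absolute log2 fold change of at least 1 (0.779) was too few to pass. Ribosome biogenesis genes, 5 of 28, were all higher, led by NOP16 at 1.14. By Fisher's exact test this list had an adjusted p of 0.0715, which does not decide. In Fisher's exact test 5 members cannot pass when all are higher, although 5 can when all are lower. Within strata of GC content and length, the ribosome biogenesis list passed by an exact test (adjusted p = 0.0258). By the same exact test the cholesterol list (adjusted p = 0.088) and the class II list (0.101) did not pass.

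Plasma cell genes were lower where they were called. The authors' deposited table held 5 of 23, all lower: LY9, a SLAM family receptor gene, at -1.29 (Q = 2.7e-08), TXNDC5 at -0.74 (89.6% of its sequence words shared with another gene), IRF4, a transcription factor on which myeloma cells depend, at -0.63 (Q = 0.00323), TNFRSF17, which encodes BCMA, at -0.48, and SDC1, which encodes CD138, at -0.45 (Q = 0.0446). Of the 35 genes for G1/S and replication, 5 were called and all were lower, with CDT1, a replication licensing gene, at -1.05 (Q = 0.000125) and RRM2, a ribonucleotide reductase subunit gene, at -0.51 in the authors' deposited table. Both lists had an adjusted p of 0.0297 over 9 lists and 0.0957 over 29 (Fisher's exact test). By an exact binomial test both had an adjusted p of 0.0703, which does not decide, since 5 members cannot pass it even when all go one way. With a Q value under 0.01, 3 plasma cell and 2 G1/S members were left, all lower (adjusted p = 0.223 and 0.28, Fisher's exact test), again too few to pass. Without genes sharing sequence the plasma cell list did not pass (4 of 4 lower, adjusted p = 0.0646, Fisher's exact test). Among 35 G2/M and mitosis genes only CKS2 was called, at 0.52, and among 15 cell cycle inhibitors and D cyclins only CDKN1C, at 1.30 (Q = 0.000578). Bone marrow adhesion and homing genes had 4 lower and 1 higher member, with CCR10 at -1.04, and the list did not pass (Fisher's exact test, adjusted p = 0.194).

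**Figure D2:**
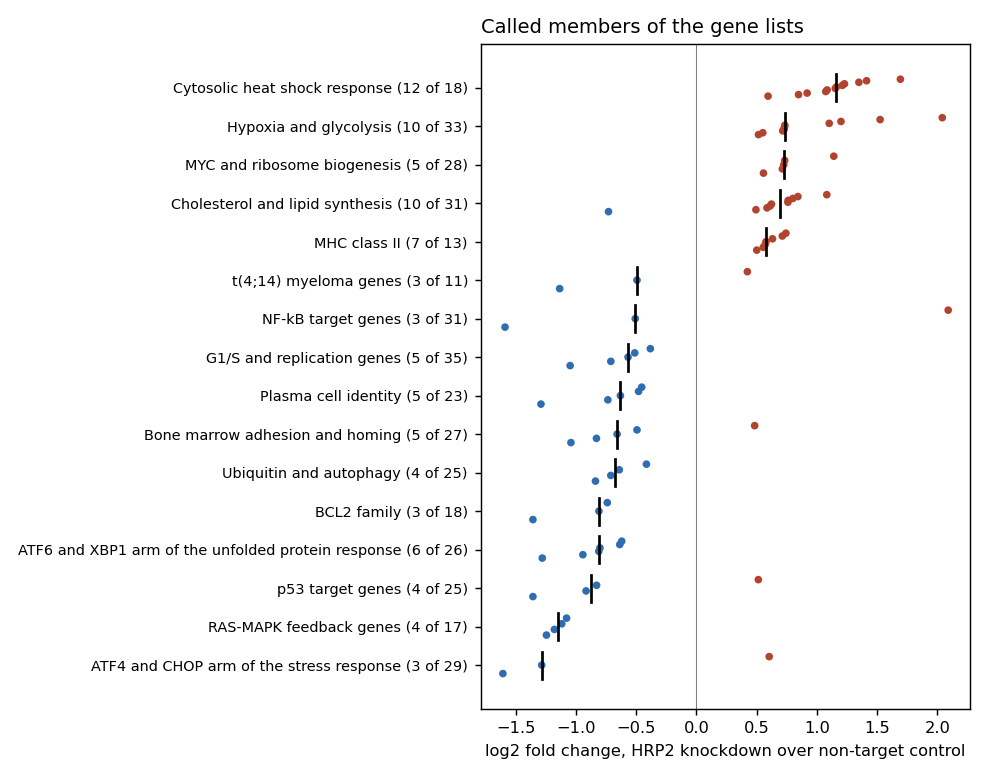
Log2 fold changes (x axis) of the called members of each gene list with at least 3 of them in the authors' deposited gene table, 1 point per gene, red higher and blue lower in the knockdown, with a black bar at the median. Labels give the called members out of the list's size; the 12 called heat shock genes and 10 called hypoxia and glycolysis genes lie to the right of 0, and the 6 called unfolded protein response genes to the left.

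Chromatin regulators were largely outside the table, as were most mRNA genes (682 called, 24237 listed). Neither the 15 H3K27 methylation enzymes and cofactors nor the 13 H3K36 methylation enzymes had a called member, and of 26 SWI/SNF subunits SMARCE1 was called at 0.57, with 63.4% of its sequence words shared, and SMARCA2 at -0.64 in the authors' deposited table. The 90 developmental transcription factors, the 22 cancer-testis antigens, the 32 WNT pathway genes, the 26 epithelial-mesenchymal and matrix genes, the 19 drug transporter and resistance genes and the 41 cytosolic ribosomal protein genes had no called member. Smaller numbers came from the t(4;14) myeloma genes (FGFR3, ITGB7 at -0.49 and MAF at 0.42, of 11), the NF-kB targets (CXCL10 at 2.09, RELB at -0.51 and PLEK at -1.59, of 31), the type I interferon genes (2 called of 29, among them IRF7 at -1.14) and the p53 targets (BBC3, TNFRSF10B and TP53INP1 lower and FAS higher, of 25), all from the authors' deposited table. Of 41 DNA double-strand break repair genes BRCA1 was called at -0.62. Of 29 oxidative phosphorylation genes it was SDHB at 0.53, of 19 histone genes HIST1H2BK at 0.88 (86.3% shared), of 21 myeloma growth and bone disease factors TNFRSF13B at -0.74, and of 23 death receptors and caspases FAS at 0.51 and TNFRSF10B at -0.92. Markers of other cell types (T and NK, myeloid, erythroid and platelet, stromal and endothelial, epithelial, and earlier B cell), 104 genes in 6 lists, had none in the table. Because genes outside the table have no value, a list without a called member is not shown to be unchanged.

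Direction went with base composition. The median transcript GC content was 57.4% for lower genes and 46.7% for higher genes, a difference of 10.7 percentage points (two-sided permutation test over genes, p = 1e-05, the smallest that 100000 permutations can give). Of the 169 called genes in the top quartile of GC content, 14.8% were higher (exact 95% binomial interval 9.8% to 21.1%), against 75.3% (68.1% to 81.6%) of the 170 in the bottom quartile. These intervals cover counting error only. Transcript length did not separate the directions (median 1835.5 nucleotides for lower and 1846 for higher genes, permutation p = 0.892). When each list was compared only with called genes of similar GC content and length, the heat shock (adjusted p = 0.00569), hypoxia and glycolysis (0.00256) and unfolded protein response (0.0258) lists passed by an exact test within strata, as did the ribosome biogenesis list (5 of 5 higher, 0.0258). The plasma cell and G1/S lists (0.0553 each), the cholesterol list (0.088) and the MHC class II list (0.101) then did not.

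**Figure D3:**
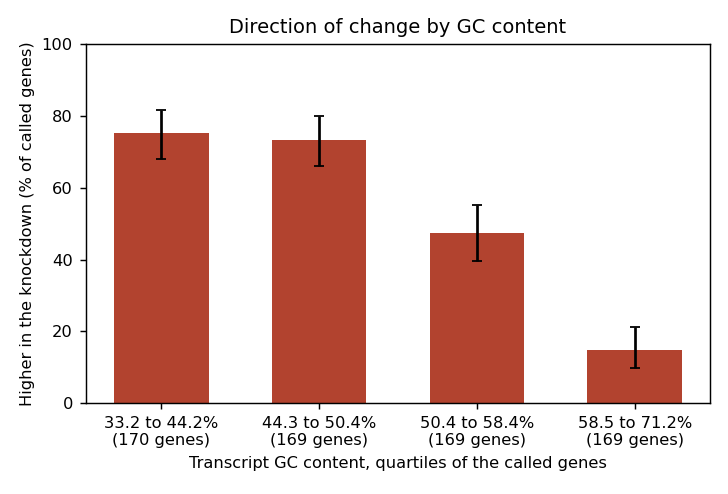
Percent of called genes that were higher in HRP2 knockdown (y axis) in each quartile of transcript GC content (x axis), with exact 95% binomial intervals as error bars. The share falls from 75.3% of 170 genes in the lowest quartile to 14.8% of 169 genes in the highest.

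At the transcript level the authors' deposited table held 1040 called transcripts, 530 higher and 510 lower, from 878 genes. Their fold changes were grouped by size, and only the group at 20 or more was set apart by a gap. The limit at 6 was chosen and is not a gap: 856 transcripts lay at 3 or more and 823 at 6 or more. An absolute log2 fold change under 6 was found for 217 transcripts, of 6 to 13 for 746, and of at least 20 for 77, with none between 13 and 20. The match with the gene table differed between these groups. Of 216 transcripts under 6 with a usable gene symbol, 36.6% (exact 95% interval 30.1% to 43.4%) came from a gene called in the same direction and 2 transcripts from a gene called in the opposite direction. Of 822 transcripts at 6 or more the share was 5.2% (3.8% to 7.0%), with 20 from a gene called in the opposite direction, and the shares differed by Fisher's exact test (two-sided p = 5.01e-30). NSD2 had 3 called transcripts, at -7.41, 10.69 and 23.89 in the authors' deposited transcript table, without being called as a gene. IRF4, lower as a gene, had one transcript at -1.04 and another at 1.93. Of the 12 called heat shock genes, 10 had called transcripts, 13 in all and each higher, with HSPH1 at 2.34, HSPA8 at 1.51 and 1.78, and DNAJA1 at 1.23 in the authors' deposited transcript table. Among these 13, transcripts of HSP90AB1 at 26.37 and AHSA1 at 10.98 were past 6, and DNAJB1 and HSPB1 had no called transcript.

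**Figure D4:**
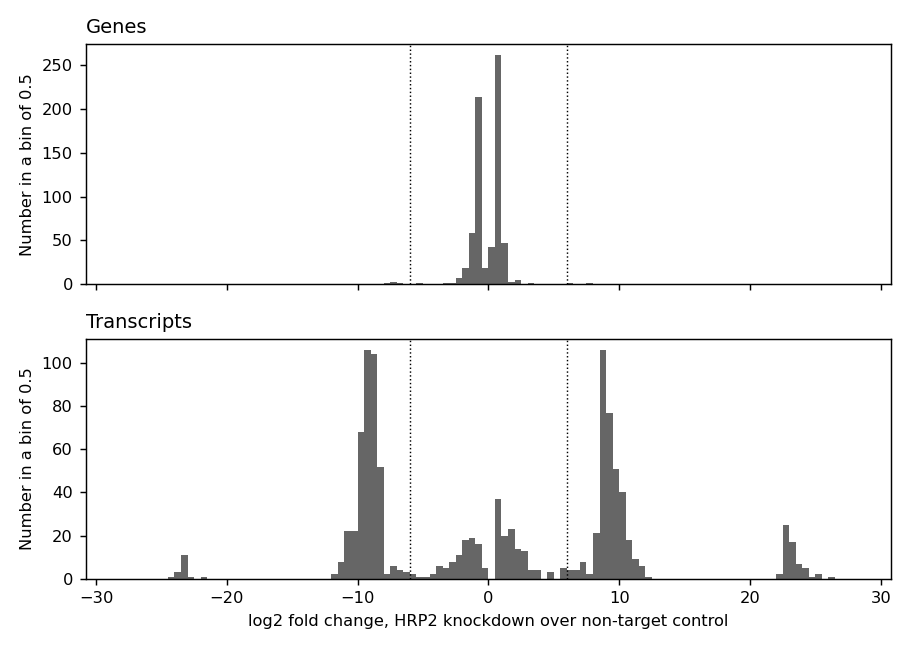
Number of called genes (upper panel) and called transcripts (lower panel) in bins of 0.5 of the log2 fold change of HRP2 knockdown over non-target control, with dotted lines at an absolute log2 fold change of 6. Genes cluster within 2 of 0, whereas 823 of 1040 transcripts lie at or beyond the dotted lines.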

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

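The alternatives with a Q value under 0.01 or an absolute log2 fold change of at least 1 were fixed before the data were examined, and the others were chosen after seeing them. No paired analysis was possible because the deposited tables hold no values per library; for the same reason the replicate block, leaving out each library, other normalizations, other count filters, DESeq2, limma, other pseudocounts and the gene set tests were not run. The count of higher genes went from 361 to 134 with a Q value under 0.01, to 58 with an absolute log2 fold change of at least 1 and to 112 genes in the transcript table (transcripts under 6 in absolute log2 fold change); the count of lower genes went from 323 to 121, 91 and 84. The first 2 of these follow from the stricter thresholds, and the last counts another set of features. Without genes sharing sequence, 341 higher and 308 lower genes remained. HDGFL2 kept its direction in the transcript table. The number of lists past the threshold, 7 at first, was 1 with a Q value under 0.01 and 1 with an absolute log2 fold change of at least 1 (the heat shock list in both), 4 with an exact binomial test, 5 without genes sharing sequence (plasma cell and cholesterol lost), 4 within strata of GC content and length, 1 without the chromosome with most members and 2 with adjustment over all 29 lists. Of the 4 within strata, 3 were among the first 7 and ribosome biogenesis was added (exact test, adjusted p = 0.0258). Most of these alternatives leave fewer called members or adjust over more lists. By the exact binomial test a list of 5 called members cannot pass even when all go one way. With a Q value under 0.01 or an absolute log2 fold change of at least 1, several lists kept too few members to pass. The heat shock list passed under each of these alternatives, with adjusted p from 0.00109 to 0.0165 (exact tests). Each alternative reuses the same deposited directions, so a list whose called members all went one way could not reverse. Of 33 named genes with a single called transcript, 31 had the same direction there, and 2 were opposite: HDAC6, -0.71 as a gene and 8.68 as a transcript, and HMGCS1, 0.76 as a gene and -8.74 as a transcript; the cause was not tested for these 2 genes. What depth limits cannot be said, since the depth is unknown.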

Other observations

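Of the tests in this part, those of shared sequence, of transcripts in opposite directions, of immediate early genes, of the RAS-MAPK genes and of direction by chromosome were chosen after the result was seen, as were the splits of the tests within GC strata and without the main chromosome into lists that passed and lists that did not.

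All of the gene groups in this paragraph had fewer than 5 called members. Of 17 genes induced as feedback by RAS-MAPK signalling, a pathway downstream of FGFR3, the authors' deposited table held 4, and all 4 were lower: DUSP4, an ERK phosphatase gene, at a log2 fold change of -1.24 (Q = 1.01e-06), ETV4 at -1.18, SPRED2 at -1.12 and ETV5 at -1.08. A candidate explanation, formed after the values were seen, is lower output of the RAS-MAPK pathway with less FGFR3. Fisher's exact test of direction gave p = 0.0492 for this list and 0.159 after adjustment over the 29 lists with a called member, so the test left this open, and 13 of the 17 genes have no value in the table. FGFR3 (62.0% GC) and ETV4 (59.9%) lie in the top quartile of GC content, where 85.2% of called genes were lower. SPRED2 (55.2%), DUSP4 (53.9%) and ETV5 (50.8%) lie in the next quartile, where 52.7% were lower. This list was not tested within strata of GC content.

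Apoptosis regulators of the BCL2 family were called in 3 of 18 cases, on both sides of the pathway. The survival genes BCL2 and BCL2L1 had log2 fold changes of -0.81 (Q = 0.0102) and -0.74 (Q = 0.0051) in the authors' deposited table, and BBC3, which encodes the pro-apoptotic PUMA, -1.36 (Q = 0.0235). TNFRSF10B, a TRAIL receptor gene, was lower at -0.92, and FAS higher at 0.51. Both called immediate early genes out of 20 were lower, NR4A1 at 0.314 times and JUND at 0.499 times the control level in the authors' deposited table. None of the 10 nearest protein-coding neighbours of HDGFL2, 5 on each side, was in the table.

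The first pattern is the GC content of the called genes, higher for lower genes by a median of 10.7 percentage points. GC bias between libraries would give such a trend, and so would a knockdown response that differs between GC-rich and GC-poor genes; without values per library these cannot be told apart. As the whole cause of direction, GC bias would leave few exceptions, but 14.8% of the top quartile were higher, with an interval whose lower end, 9.8%, fell just short of the bound of 10% set for excluding it. Direction also differed between chromosomes (permutation p = 1e-05, the smallest that 100000 permutations can give), from 21.2% higher on chromosome 17 to 85.7% on chromosome 10, and within deciles of GC content the same test gave p = 0.0768.

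The second pattern is the set of lists whose called members went one way, for which the tests argue against GC content or length as the whole cause in 3 cases, heat shock, hypoxia and glycolysis, and unfolded protein response, which stayed past the threshold within strata; for the other 4 the lowest adjusted p was 0.0553 and it remains open. When the chromosome with most called members was left out, 1 list, heat shock, stayed past the threshold (adjusted p = 0.0165, Fisher's exact test), which argues against a copy number difference of one chromosome as the whole cause for that list. For 5 others adjusted p was 0.11 to 0.145 (Fisher's exact test) with fewer members left. These went the same way in 6 of 6 cases for hypoxia and glycolysis, 4 of 4 for the unfolded protein response and for G1/S, 3 of 3 for plasma cell genes and 7 of 8 for cholesterol. Since lists were picked for going one way, this test does not decide. However, the called members lay on 7 chromosomes for hypoxia and glycolysis and for cholesterol. They lay on 5 for G1/S, and on 4 for the unfolded protein response and for plasma cell genes. Gene dosage of one chromosome reaches only the members on it, which argues against it as the whole cause for these 5 lists. A part in them remains open. For the MHC class II genes, all on 1 chromosome, the explanation remains open. A culture or handling difference between the groups may also raise heat shock and hypoxia genes, and with them immediate early genes, of which 0 were called higher and 2 lower, too few to decide. An effect of HRP2 loss itself stays among the open explanations.

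The third pattern is the extreme fold changes. At the gene level, 6 of the 8 genes with an absolute log2 fold change of at least 3 and a sequence to compare shared it with another gene or were readthrough loci, against 29 of 669 other genes (Fisher's exact test, p = 3.22e-07), consistent with reads shared between overlapping or near-identical genes. At the transcript level, few extreme transcripts had a gene called in the same direction (5.2% against 36.6%, Fisher's exact test, p = 5.01e-30). The same reads being assigned to another transcript of the gene would give this. So would transcripts too low in abundance to move the gene total. Without transcript levels the test cannot tell these apart. Of 87 genes with at least 2 extreme transcripts, 56 held both directions, against a mean of 47.3 when directions were shuffled (permutation p = 0.0345); FAN1, NFAT5 and POGZ are examples, with NFAT5 at 23.21 and -23.32 in the authors' deposited transcript table. A change in transcript use upon knockdown would give the same picture and was not tested.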
